A study of Mus musculus with 9 samples.

How the data were processed

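RNA of bone marrow-derived dendritic cells from BALB/c mice was measured in 9 libraries, 3 each of control (phosphate-buffered saline, per the series' design text), PEG-MP and PEG-IM-MP. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected, and paired-end libraries were read on an Illumina NovaSeq instrument. The genome build GRCm38 and the tools Bowtie2 and StringTie are named in the submitters' processing notes, and their versions are not given in the sources used here. The strand setting is likewise not given in the sources used here, so a gene and its antisense partner are not told apart.

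The authors deposited TPM per transcript in 1 table, an abundance corrected for transcript length and scaled to the same total in each library. TPM keeps no read totals, so the depth of each library, counting intervals and limits for values of 0 are unknown, and a value of 0 can be a failed estimate. The table holds 154636 transcripts under 55416 gene symbols; 1053 transcripts have no symbol and 12774 have an identifier from assembly, and 24 symbols are stored as dates. Of the transcripts, 141767 are in GENCODE M21, all with identical lengths, and coordinates of genes come from that annotation of GRCm38. The authors' deposited group means differed from the means of the libraries by at most 3.3e-05 TPM. Because TPM is relative, a rise of some abundant transcripts lowers all others, and reads of near-identical copies can be exchanged.

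Groups were taken from the labels. TPM was summed per gene symbol, and transcripts without a symbol stayed out of the gene tests but not out of the scale. Genes with at least 1 TPM in at least 3 of the 9 libraries were tested (13564 genes) on log2(TPM + 1), a pseudocount of 1. limma 3.58.1 in R 4.3.3 (statmod 1.5.0) was fitted to all 9 libraries with group as the only term and a mean-variance trend, with 6 residual and 2.90 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each of 3 comparisons, and 0.05 was the threshold. The moderated F test asked whether a gene differed among the groups. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

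The design, the alternatives, the rule for named genes and the 31 gene lists were fixed before the data were examined, except where stated. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and repeated with an estimated correlation, with which camera called 0 lists in each comparison, while 6 for PEG-MP against control, 3 for PEG-IM-MP against control and 1 for PEG-IM-MP against PEG-MP had an unadjusted p under 0.05 and fry called 26, 29 and 30. Limma's fry asks whether the genes of a list move one way on balance and compares them with no other genes. The lists cover interferon-stimulated genes, cytokines, chemokines, NF-kB, maturation, MHC class I and II, pattern recognition, inflammasome, phagocytosis, cholesterol, lipid storage, lysosome, glycolysis, oxidative phosphorylation, cell cycle, unfolded protein response, Nrf2, alternative activation, p53, immediate early and heat shock (fixed as a sign of handling stress), ribosomal proteins, mitochondrially encoded genes and markers of other cells (macrophage, neutrophil, mast cell, lymphocyte, plasmacytoid and conventional dendritic cell, erythroid, stromal and epithelial).

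Named genes are, for each comparison, the 6 with the largest rise and the 6 with the largest fall among called genes with a mean of at least 5 TPM and no overlap between the libraries of the groups, leaving out symbols of predicted genes. To these come a fixed set (Il6, Tnf, Il1b, Il12b, Il10, Ifnb1, Cxcl10, Ccl5, Cd40, Cd80, Cd86, Ccr7, H2-K1, H2-Ab1), up to 4 members of each list with the smallest p, and up to 2 markers with the highest mean TPM of each list of other cells. A result of 1 list member is not reported here.

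Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-of-ratios scaling, quantile normalization, the most abundant transcript only, the replicate number as a block, array quality weights, no trend, only the 6 libraries compared, and each library left out in turn. Annotated transcripts only, and list tests after median-of-ratios scaling, were added after the data had been seen. The procedure was tested on simulated data for PEG-MP against control, with 200 of 13564 genes changed: it recovered 40.3% of genes at a log2 change of 0.5, 83.6% at 1 and 97.0% at 2, with 8 false calls among 155, and it called the 1 shifted list and 0 of the others. The simulated genes varied independently of each other. In the data the estimated correlation between the interferon-stimulated genes was 0.667. The simulation therefore cannot show how many lists camera calls falsely when genes move together. Its changes were set on the log scale without rescaling to a fixed total, and in far fewer genes than were called in the data. Its false calls therefore do not measure calls that a shift of the TPM scale creates. KEGG pathways were taken from the deposited annotation columns and tested with camera as an exploration.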

Results

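Bone marrow-derived dendritic cells of BALB/c mice were treated with phosphate-buffered saline (control) or with 1 of 2 nanovesicle preparations, named PEG-MP and PEG-IM-MP in the labels, and their poly(A) RNA was sequenced. Dendritic cells are the immune cells that take up material, present its peptides on MHC molecules and prime T cells. Each of the 3 groups held 3 libraries. The series is described as a study of the immune response to nanovesicle vaccines, and the comparisons ask which genes differ between each preparation and the control, and between the preparations. Values are TPM, a transcript abundance corrected for length and scaled to the same total in every library. They are summed per gene symbol and given as mean ± SD over the libraries of a group (SD, n = 3). Coordinates are those of GRCm38. TPM carries no read totals, so the depth of each library is unknown and no counting interval can be given. Nothing in the labels says that the replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

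The control libraries held 12802 ± 57.3 genes at 1 TPM or more, the PEG-MP libraries 12766 ± 49.7 and the PEG-IM-MP libraries 11555 ± 48.3. Transcripts of the mitochondrial chromosome took 5.52 ± 0.043% of TPM in control, 4.002 ± 0.267% in PEG-MP and 4.32 ± 0.188% in PEG-IM-MP. The gene with the most TPM was Lyz2 in the control libraries and Fth1 in the treated ones. Pearson correlations across genes ran from 0.981 to 0.987 within groups and from 0.786 to 0.927 between groups. The first principal component held 73.7% of the variance and separated PEG-IM-MP from the rest, and the second held 17.0% and separated PEG-MP from control. Of 13564 genes tested, 12061 (88.9%) differed among the 3 groups in limma's moderated F test.

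**Figure D1:**
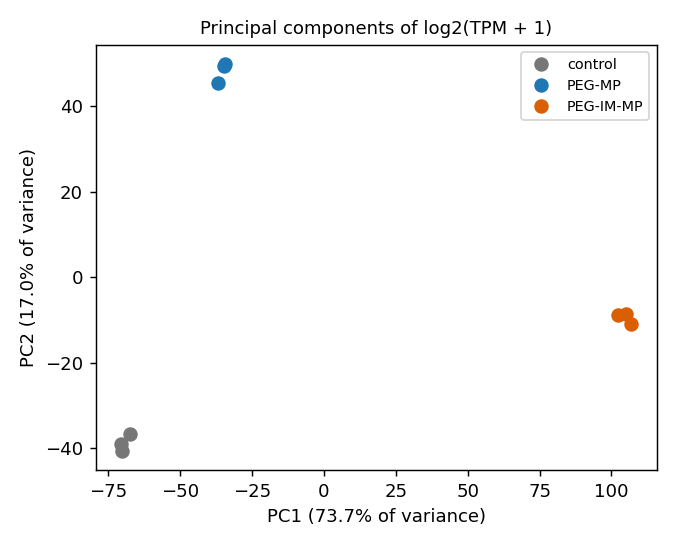
Principal components of log2(TPM + 1) over the 13564 tested genes. Each point is 1 library, the horizontal axis is PC1 (73.7% of variance) and the vertical axis is PC2 (17.0% of variance); the 3 libraries of each group lie together and apart from the other groups.

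The inflammatory transcripts Saa3, Nos2 and Il6 were far higher in PEG-MP than in control. Saa3, which encodes an acute-phase serum amyloid protein (gene ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), was at 107 ± 10.6 TPM in control and 29653 ± 3681 TPM in PEG-MP. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), stood at 0.707 ± 0.388 and 278 ± 38.3 TPM, and Il6, an inflammatory cytokine (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), at 1.25 ± 0.344 and 170.3 ± 26.4 TPM. In the other direction Ccr2, a chemokine receptor of monocytes (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), was at 780.0 ± 90.6 TPM in control and 11.6 ± 1.41 TPM in PEG-MP. The genes higher in PEG-MP, and then those lower, numbered 36 and 0 of 40 interferon-stimulated, 22 and 0 of 23 NF-kB, 19 and 1 of 22 MHC class I and 22 and 1 of 24 maturation genes. They numbered 2 and 23 of 32 cell cycle and 0 and 34 of 34 cytosolic ribosomal protein genes, and camera called each of these 6 lists, which had an adjusted p between 0.17 and 0.275 with an estimated correlation.

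The 6 largest rises among the genes the naming rule admits were led by U90926 (log2 fold change 8.16, SE 0.129, adjusted p = 1.37e-09) and Saa3 (log2 fold change 8.10, SE 0.0957, adjusted p = 4.17e-10). The others were Nos2 (7.37), the scavenger receptor Marco (6.60), Il6 (6.25) and Il12a, a subunit of a T cell-directing cytokine (5.90). The 6 largest falls were Ccr2 (log2 fold change -5.95, SE 0.113, adjusted p = 4.83e-09), the kallikrein Klk1b11 (-5.21), the lectin gene Asgr2 (-4.73), the ribonuclease Ear2 (-4.44), the lectin gene Mgl2 (-4.26) and the mitotic cyclin Ccnb2 (-4.04). All fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM.

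Of 22 measured inflammatory cytokines 16 rose and 6 fell (camera adjusted p = 3.61e-05). Il1b rose from 141 ± 42.7 to 2570.0 ± 282 TPM, Il1a from 9.42 ± 1.04 to 222 ± 52.5 TPM and Il12b from 5.08 ± 0.586 to 303 ± 119 TPM. Tnf rose from 6.39 ± 1.28 to 34.9 ± 10.1 TPM. Il10 was at 0.11, 0.07 and 0 TPM in the control libraries and 2.41, 3.59 and 0.76 in PEG-MP, and Ifnb1 at 0.12, 0 and 0.14 in control and 0.14, 0.49 and 0 in PEG-MP, so neither passed the filter on low values. Of 20 chemokines 13 rose and 2 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.000732). Ccl5 went from 685 ± 49.4 to 31811 ± 3136 TPM and the neutrophil-attracting Cxcl3 from 43.2 ± 19.2 to 2316 ± 338 TPM, Cxcl10 rose by a log2 value of 1.36, and Ccl6 fell from 3666 ± 473 to 504 ± 50.3 TPM. Of 23 NF-kB pathway genes 22 rose and 0 fell (camera adjusted p = 7.56e-14). Sod2 went from 115 ± 25.8 to 1740.0 ± 81.4 TPM, Traf1 from 38.3 ± 3.91 to 229.6 ± 14.6 TPM and the feedback inhibitor Tnfaip3 from 15.6 ± 1.24 to 110.4 ± 14.7 TPM. With an estimated correlation between genes the adjusted p was 0.274 for the cytokines, 0.275 for the chemokines and 0.170 for the NF-kB list.

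Interferon-stimulated genes rose without exception among those past the threshold. Of 40, 36 rose and 0 fell (37 and 0 adjusted over the list alone), with a median log2 fold change of 1.21 (camera adjusted p = 9.08e-14, and adjusted p = 0.275 with an estimated correlation). Irf7, a transcription factor of the interferon response, went from 81.2 ± 3.28 to 695 ± 101 TPM, Isg15 from 41.1 ± 0.961 to 369 ± 112 TPM and the GTPase gene Gbp2 from 44.5 ± 2.37 to 254 ± 55.9 TPM. Of 24 maturation genes 22 rose and 1 fell (23 and 1 adjusted over the list alone, camera adjusted p = 3.72e-12). The costimulatory molecules Cd40 and Cd80 rose from 5.70 ± 3.97 to 71.9 ± 10.3 TPM and from 10.9 ± 0.394 to 47.8 ± 10.3 TPM. Cd86 rose from 52.9 ± 6.47 to 85.1 ± 6.38 TPM, and Ccr7, the receptor that directs dendritic cells to lymph nodes, rose from 122 ± 14.8 to 528 ± 33.0 TPM. Of 22 MHC class I presentation genes 19 rose and 1 fell (camera adjusted p = 1.14e-10). H2-K1 stood at 2524 ± 89.2 and 5009 ± 315 TPM. H2-Q7 also rose (1.92), but genes of its family are near-identical copies whose reads can be exchanged, and assembled transcripts held 67.9% of its TPM. With an estimated correlation the adjusted p was 0.170 for the maturation list and 0.231 for the MHC class I list. Of 17 MHC class II presentation genes 2 rose and 9 fell (camera adjusted p = 0.0384, and adjusted p = 0.275 with an estimated correlation). This call ended with quantile normalization (0.105), with a filter at 5 TPM (0.0501) and without PEG-MP replicate 1 (0.0689), PEG-MP replicate 3 (0.0557) or PEG-IM-MP replicate 2 (0.0535). It also ended with the replicate number as a block. Cd74, the invariant chain, was lower (-0.63) while H2-Ab1 stood at 1369 ± 73.1 and 1374 ± 137 TPM.

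Of 32 cell cycle genes 2 rose and 23 fell (camera adjusted p = 7.19e-09). Ube2c went from 88.7 ± 2.09 to 6.12 ± 0.490 TPM and Cdc20 from 38.7 ± 4.05 to 2.68 ± 0.199 TPM. All 34 measured cytosolic ribosomal protein genes fell (33 after quantile normalization), with a median log2 fold change of -0.60 (camera adjusted p = 7.43e-17). Of 21 glycolysis genes 18 rose and 1 fell (camera adjusted p = 1.30e-08), including Pgk1 (1.35) and the regulator Pfkfb3 (1.49). Nrf2 targets rose in 13 and fell in 4 of 20 genes (14 and 4 adjusted over the list alone, camera adjusted p = 0.00131). The heme-degrading enzyme Hmox1 went from 225 ± 17.2 to 689.7 ± 26.6 TPM. Unfolded protein response genes rose in 10 and fell in 1 of 21 (12 and 1 adjusted over the list alone, camera adjusted p = 0.00206). Cholesterol biosynthesis genes rose in 10 and fell in 2 of 23 (camera adjusted p = 0.0183, 0.0557 without PEG-MP replicate 3 and 0.0501 with a filter at 5 TPM). Lysosome genes rose in 6 and fell in 20 of 32 (7 and 20 adjusted over the list alone, camera adjusted p = 0.00151). Psap went from 11894 ± 556 to 5320.0 ± 68.9 TPM. These 7 lists had an adjusted p between 0.17 and 0.485 with an estimated correlation.

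Signs of other cells and of RNA quality moved with the treatment. Macrophage markers fell in 9 and rose in 2 of 13 (camera adjusted p = 0.00116). Lyz2 went from 46183 ± 1468 to 10072 ± 1083 TPM and the complement gene C1qa from 614 ± 36.1 to 59.2 ± 4.52 TPM, while Marco rose. Csf1r stood at 878 ± 83.4 and 686 ± 90.4 TPM, a fall that was not called on its most abundant transcript alone (adjusted p = 0.467). Neutrophil markers fell in 11 and rose in 1 of 14 (camera adjusted p = 0.000153). S100a9 went from 5353 ± 565 to 1001 ± 333 TPM and Lcn2 from 256 ± 45.2 to 4430.2 ± 134 TPM. Mitochondrially encoded genes, which share reads with nuclear copies, fell in 8 and rose in 2 of 15 (camera adjusted p = 0.0435, and 0.1 after quantile normalization), and mt-Cytb was lower (-0.99). That list's adjusted p was 0.0624 without control replicate 1, 0.0578 without PEG-MP replicate 3, and 0.0547, 0.0578 and 0.05 without PEG-IM-MP replicates 1, 2 and 3, so that the call ended each time. The call also ended with the replicate number as a block. With an estimated correlation the adjusted p of the macrophage, neutrophil and mitochondrially encoded lists lay between 0.17 and 0.482.

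The remaining lists were not called against the control. Genes past the threshold, higher and then lower, numbered 8 and 9 of 28 pattern recognition receptors (camera adjusted p = 0.905), 10 and 5 of 17 inflammasome genes (0.114), and 11 and 10 of 28 phagocytosis genes (0.936). They numbered 6 and 10 of 20 LXR and lipid storage genes (0.202), 6 and 7 of 30 oxidative phosphorylation genes (0.936), and 7 and 9 of 19 alternative activation genes (0.285). They numbered 6 and 7 of 21 p53 genes (0.936) and 8 and 9 of 22 immediate early and heat shock genes, a sign of handling stress (0.936). Of markers of other cells they numbered 3 and 2 of 11 mast cell markers (0.677), 0 and 2 of 6 lymphocyte markers (0.354), and 3 and 0 of 7 plasmacytoid dendritic cell markers (0.251). For the rest the counts were 4 and 3 of 12 conventional dendritic cell markers (0.655), 1 and 0 of 4 erythroid markers (0.543) and 3 and 1 of 6 stromal and epithelial markers (0.277). Single members moved far: the lectin receptor Clec4e rose from 43.9 ± 5.61 to 566 ± 35.3 TPM (43.9% of its TPM in assembled transcripts), Mrc1 fell from 94.8 ± 16.4 to 5.16 ± 0.675 TPM, and Apoe, which carries lipids, fell from 19500.0 ± 1451 to 2018 ± 169 TPM. Adjusted over the list alone, 6 and 11 of the lipid storage, 8 and 9 of the alternative activation, 7 and 7 of the p53 and 0 and 3 of the lymphocyte genes passed. Lists for which no such count is given had the same counts both ways. Median and mean differed in sign, or from the side of the test, for the phagocytosis, oxidative phosphorylation, immediate early and both dendritic cell lists.

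In all, limma called 6519 genes between PEG-MP and control, 3202 higher and 3317 lower, and 1695 of them changed at least 2-fold (851 higher, 844 lower). Over all 13564 tested genes, the 3 libraries of one group did not overlap those of the other for 7879 (58.1%), where chance gives 10% for 3 against 3.

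Transcripts of Cxcl2, Ptgs2 and Hspa1a were far higher in PEG-IM-MP than in control. Cxcl2, a neutrophil-attracting chemokine (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938), stood at 38.4 ± 16.3 TPM in control and 11555 ± 281 TPM in PEG-IM-MP. Ptgs2, the inducible prostaglandin synthase (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), stood at 1.70 ± 0.797 and 2238 ± 139.9 TPM, and the inducible heat shock gene Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) at 0.920 ± 0.723 and 687 ± 33.8 TPM. Ccr2 fell to 0.733 ± 0.138 TPM and Lyz2, the lysozyme of macrophages and related cells, from 46183 ± 1468 to 1319 ± 69.4 TPM. Hspa1a belongs to a list of immediate early and heat shock genes that was fixed as a sign of handling stress. That list rose in 13 and fell in 7 of 22 genes, and the genes higher and then lower numbered 17 and 4 of 22 cytokines, 14 and 3 of 20 chemokines and 14 and 4 of 21 unfolded protein response genes. They were 1 and 15 of 17 MHC class II, 2 and 30 of 32 cell cycle and 2 and 11 of 13 macrophage marker genes, and camera called each of these 7 lists, which had an adjusted p between 0.283 and 0.486 with an estimated correlation.

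Most genes had lower TPM in this group. The median log2 fold change over all tested genes was -0.58 against control, and -0.01 after median-of-ratios scaling, which puts the typical gene at no change. Each list's count is therefore followed by the one after that scaling, whose list tests were chosen after the data had been seen, and for several lists by the one after quantile normalization. limma called 11316 genes, 3295 higher and 8021 lower, and 6478 at least 2-fold (1701 higher, 4777 lower). After median-of-ratios scaling it called 10884, 5464 higher and 5420 lower, with 2985 and 2795 at least 2-fold, and after quantile normalization 10671, 4866 higher and 5805 lower. Of the 11316 genes, 811 were called the opposite way after median-of-ratios scaling. Over all tested genes the libraries of the groups did not overlap for 11443 (84.4%), where chance gives 10%.

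The 6 largest rises were Ptgs2 (log2 fold change 9.74, SE 0.219, adjusted p = 9.51e-10), the chemokine Cxcl1 (9.63), the activin subunit Inhba (8.74), Hspa1a (8.55), Cxcl2 (8.27) and Hspa1b (8.26), and Hspa1a and Hspa1b are near-identical copies whose reads can be exchanged. Assembled transcripts held 35.3% of the Hspa1a TPM. All 6 genes were also above every control library in PEG-MP, where Ptgs2 stood at 69.5 ± 14.7 and Cxcl1 at 295 ± 47.6 TPM. The 6 largest falls were Ccr2 (log2 fold change -8.81, SE 0.113, adjusted p = 2.36e-10), Ear2 (-6.71), the endosomal RNA sensor Tlr8 (-6.59), Mgl2 (-6.18), the selenium carrier Selenop (-6.04) and Pld4 (-5.99).

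Inflammatory cytokines rose in 17 and fell in 4 of 22 genes (18 and 3 after scaling, camera adjusted p = 4.31e-07). Il6 reached 375 ± 11.2 TPM, Il1b 3317 ± 131, Il1a 1006 ± 29.5 and Il12b 540.4 ± 66.7 TPM, Tnf stood at 34.7 ± 2.34 TPM, and Il16 fell from 33.8 ± 0.818 to 0.507 ± 0.0503 TPM. Il10 was at 0.71, 0.4 and 0.87 TPM and Ifnb1 at 0.14, 1.25 and 0.68 TPM in the PEG-IM-MP libraries, below the filter. Chemokines rose in 14 and fell in 3 of 20 (15 and 2 after scaling, camera adjusted p = 8.95e-06). Cxcl3 stood at 10871 ± 111, Ccl5 at 5574 ± 353 and Cxcl10 at 72.8 ± 2.62 TPM. NF-kB pathway genes rose in 17 and fell in 3 of 23 (20 and 1 after scaling, camera adjusted p = 2.38e-07). Malt1 went from 22.3 ± 1.22 to 1174 ± 20.7 TPM. Maturation genes rose in 14 and fell in 6 of 24 (19 and 4 after scaling, camera adjusted p = 0.000173). Cd80 stood at 282 ± 12.3, Cd86 at 262 ± 18.7, Cd40 at 39.2 ± 3.06 and Ccr7 at 353 ± 25.5 TPM, and the checkpoint ligand Cd274 went from 98.7 ± 3.56 to 844 ± 23.2 TPM. The adjusted p lay between 0.283 and 0.467 for these 4 lists with an estimated correlation.

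Unfolded protein response, immediate early and heat shock, p53 and glycolysis lists were called higher than in control, and Nrf2 targets of oxidative stress were not. Unfolded protein response genes rose in 14 and fell in 4 of 21 (20 and 0 after scaling, camera adjusted p = 1.31e-05). The transcription factors Atf4 and Atf3 went from 95.2 ± 4.69 to 676 ± 6.77 TPM and from 75.8 ± 10.6 to 834 ± 128 TPM, and the chaperone Hspa5 from 189 ± 26.9 to 1236 ± 50.1 TPM. Immediate early and heat shock genes, the list fixed as a sign of handling stress, rose in 13 and fell in 7 of 22 (16 and 5 after scaling, camera adjusted p = 0.00214). Hsph1 went from 16.5 ± 1.45 to 214 ± 16.7 TPM. The p53 and apoptosis genes rose in 11 and fell in 7 of 21 (15 and 4 after scaling, camera adjusted p = 0.0210, and 0.0637 after quantile normalization). On annotated transcripts alone 9 were higher and 11 lower. Mdm2 went from 97.5 ± 2.58 to 1219.5 ± 82.1 TPM. Glycolysis genes rose in 11 and fell in 7 of 21 (16 and 3 after scaling, camera adjusted p = 0.0217, and 11 and 7 with an adjusted p of 0.345 after quantile normalization), with the glucose transporter Slc2a1 higher (2.16) and Pfkl lower (-1.47). These 4 lists had an adjusted p between 0.283 and 0.761 with an estimated correlation.

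MHC class II presentation genes fell in 15 and rose in 1 of 17 (12 and 2 after scaling, camera adjusted p = 0.00759). H2-Ab1 went from 1369 ± 73.1 to 376 ± 15.5 TPM, Cd74 from 4104 ± 200.4 to 971 ± 9.01 TPM and the peptide exchange gene H2-DMa from 322 ± 19.8 to 23.3 ± 0.478 TPM. Cell cycle genes fell in 30 and rose in 2 of 32 (29 and 2 after scaling, camera adjusted p = 3.91e-05). Macrophage markers fell in 11 and rose in 2 of 13 (10 and 2 after scaling, camera adjusted p = 0.0321). C1qa stood at 9.21 ± 1.17 TPM. Oxidative phosphorylation genes fell in 27 and rose in 1 of 30 (15 and 8 after median-of-ratios scaling and 27 and 2 after quantile normalization, camera adjusted p = 0.00389, which was 0.443 after median-of-ratios scaling, while quantile normalization kept the call). Ndufb8 went from 176 ± 9.13 to 67.0 ± 4.54 TPM. The cytosolic ribosomal protein genes turned with median-of-ratios scaling and not with quantile normalization: 31 of 34 were lower and 0 higher as deposited (camera adjusted p = 0.0210, and 0.0552 without PEG-IM-MP replicate 1), 29 were higher and 1 lower after median-of-ratios scaling (adjusted p = 0.000636), and 1 was higher and 32 lower after quantile normalization, where the list was called lower again. The adjusted p lay between 0.283 and 0.761 for these 5 lists with an estimated correlation.

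Interferon-stimulated genes were not called as a list against control: 6 were higher and 33 lower of 40 (14 and 22 after scaling, 7 and 29 after quantile normalization, camera adjusted p = 0.107, 0.00909 after quantile normalization and 0.0385 without PEG-MP replicate 3). Mx1 fell from 62.8 ± 7.70 to 2.90 ± 0.503 TPM and Gbp2 stood at 44.5 and 9.21 TPM, while Irf7 and Isg15 stood at 112 ± 5.42 and 203 ± 4.52 TPM. MHC class I presentation genes were higher in 6 and lower in 14 of 22 (13 and 6 after median-of-ratios scaling and 6 and 13 after quantile normalization, camera adjusted p = 0.880). H2-K1 stood at 4212 ± 113 TPM (0.74, and -0.034 on its most abundant transcript alone), and the immunoproteasome gene Psmb8 fell from 310.1 ± 9.87 to 124 ± 1.02 TPM.

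Of the other uncalled lists, the genes higher and then lower numbered 8 and 19 of 28 pattern recognition receptors (camera adjusted p = 0.666, then 10 and 15 after scaling), 8 and 8 of 17 inflammasome genes (0.443, then 10 and 6), and 9 and 18 of 28 phagocytosis genes (0.821, then 11 and 12). In lipid metabolism they numbered 9 and 13 of 23 cholesterol biosynthesis genes (0.542, then 12 and 10), and 6 and 11 of 20 lipid storage genes (0.855, then 8 and 10). They were 13 and 17 of 32 lysosome genes (0.618, then 18 and 13), 8 and 11 of 20 Nrf2 targets (0.666, then 9 and 9) and 8 and 9 of 19 alternative activation genes (0.618, then 10 and 9). Mitochondrially encoded genes were higher in 3 and lower in 8 of 15 (0.666, then 5 and 7). At least 2-fold on deposited TPM, 1 of them was higher and 6 were lower, against 1 and 1 in PEG-MP. Neutrophil markers were higher in 1 and lower in 13 of 14 (camera adjusted p = 0.0579, 0.00587 after scaling, 0.00909 after quantile normalization and 0.0364 without PEG-MP replicate 3). Mast cell markers were higher in 2 and lower in 8 of 11 (0.618), and lymphocyte markers in 0 and 5 of 6 (0.17, and 0.0344 after scaling). Plasmacytoid markers were higher in 2 and lower in 3 of 7 (0.618), conventional dendritic cell markers in 4 and 5 of 12 (0.618), erythroid markers in 1 and 2 of 4 (0.666) and stromal and epithelial markers in 2 and 2 of 6 (0.542). After median-of-ratios scaling these became 2 and 7 for mast cell, 0 and 5 for lymphocyte, 5 and 2 for plasmacytoid, 5 and 4 for conventional dendritic cell, 1 and 1 for erythroid and 3 and 2 for stromal and epithelial markers. With quantile normalization the lysosome genes numbered 13 and 17, the cholesterol genes 10 and 9, the inflammasome genes 9 and 8, the alternative activation genes 8 and 10, the plasmacytoid markers 3 and 3, the conventional dendritic cell markers 7 and 5, the erythroid markers 1 and 0 and the stromal and epithelial markers 4 and 2. Among single markers Hdc, the histamine-forming enzyme, rose from 4.17 ± 0.947 to 96.6 ± 3.12 TPM and Prss34 fell from 26.8 ± 2.71 to 1.15 ± 0.240 TPM. Adjusted over the list alone the counts of the 31 lists were the same but for alternative activation, with 8 and 10. Medians were negative while the test pointed up for the MHC class I, inflammasome, cholesterol, lysosome, Nrf2, alternative activation, erythroid and both dendritic cell lists, since camera compares a list with the other genes.

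**Figure D2:**
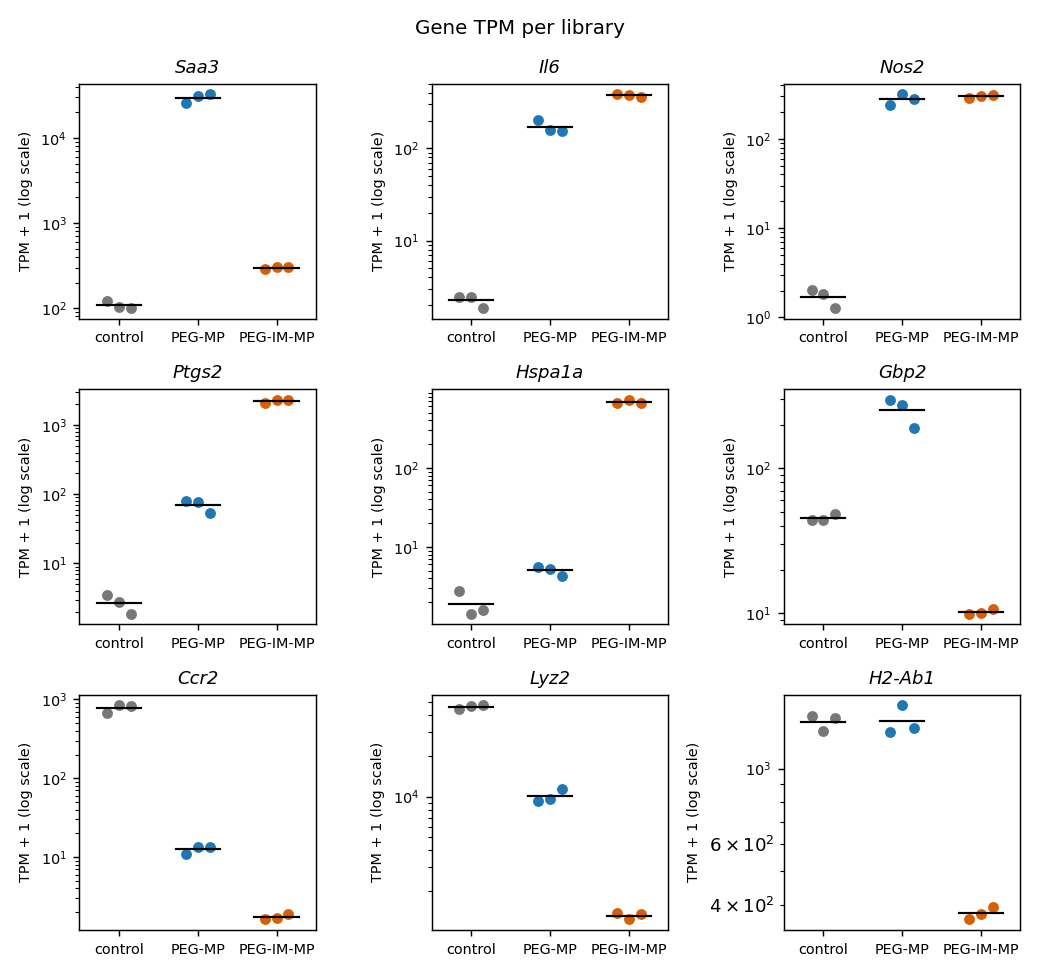
TPM + 1 of 9 genes on log axes, 1 point per library and a black line at each group's mean, for control, PEG-MP and PEG-IM-MP. Saa3 was highest in PEG-MP and Ptgs2 and Hspa1a in PEG-IM-MP, Il6 and Nos2 were high in both, and Ccr2 and Lyz2 were lower in both than in control. Ptgs2 was also above control in PEG-MP (69.5 TPM, against 1.70 in control), and Saa3 in PEG-IM-MP (299 TPM, against 107 in control).

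**Figure D3:**
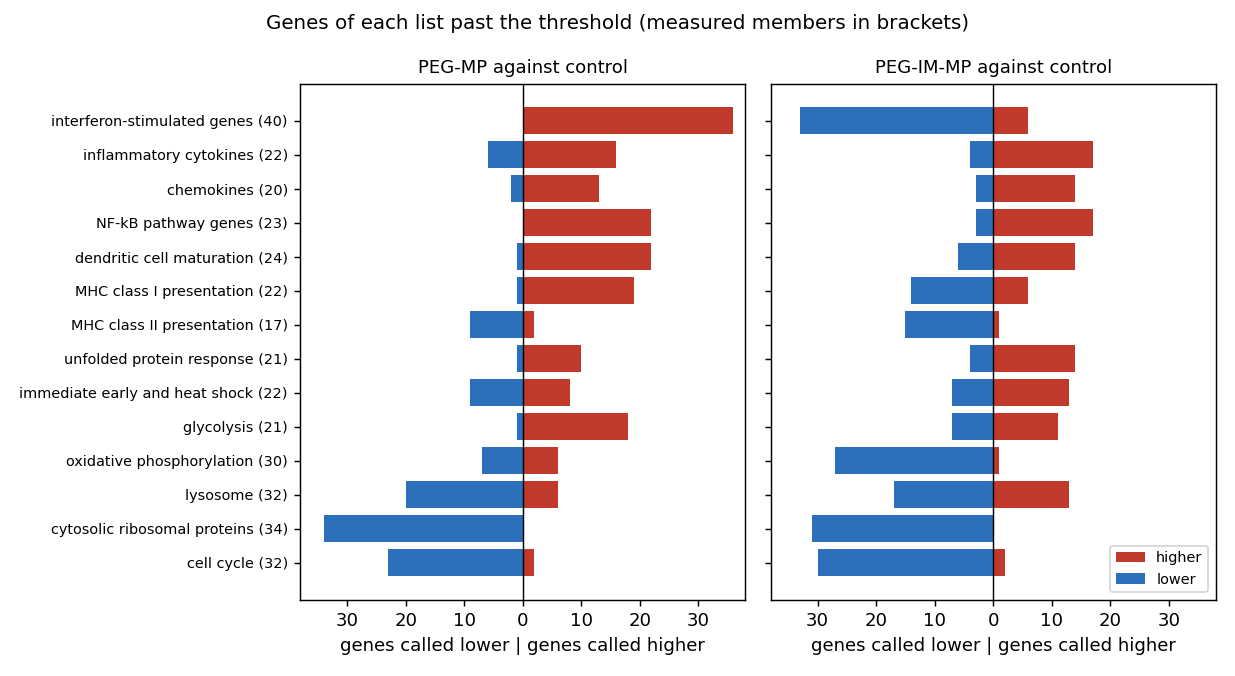
Number of genes of each of 14 lists that limma called higher (right) or lower (left) than control, on deposited TPM, for PEG-MP and for PEG-IM-MP, with the number of measured members in brackets. In PEG-IM-MP the cytosolic ribosomal protein bar turns to the right after median-of-ratios scaling (29 higher, 1 lower) and not after quantile normalization (1 higher, 32 lower), and the MHC class I and lysosome counts become 13 and 18 higher and 6 and 13 lower after the first and 6 and 13 higher and 13 and 17 lower after the second.

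The fold changes of the treatments against control shared a direction in part. All values of this paragraph are on deposited TPM and were not repeated under other scalings. After median-of-ratios scaling 811 of the 11316 calls of PEG-IM-MP against control turned, so the counts by direction depend on the scale. Of the genes called in both comparisons, 1581 were higher and 2740 lower in both, where independent lists of these sizes would share 778 and 1962, and 1468 went opposite ways, against 2699. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.54 and their covariance 0.624. Groups with no effect, simulated against the shared controls, gave an r of 0.501, a covariance of 0.0201 and at most 0 shared calls, so the covariance exceeded the simulated one by 0.604. The fold changes had the same sign for 63.9% of genes, against 66.6% in the simulation. The simulated genes had no effects, so their r and share of equal signs come from the shared controls alone. In the data 6519 and 11316 genes were called, so the simulated r and share do not show what unrelated effects would give. They are no measure of whether the treatments agree. The simulation already holds the spread seen between the shared control libraries. A deviation common to all 3 controls is not in it, and it cannot be tested, as they cannot be split into parts of 2 or more libraries.

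Compared directly, the genes higher and then lower in PEG-IM-MP than in PEG-MP numbered 12 and 3 of 21 unfolded protein response genes, 14 and 5 of 22 immediate early and heat shock genes, fixed as a sign of handling stress, and 0 and 38 of 40 interferon-stimulated genes. Camera called each of these 3 lists, which had adjusted p = 0.473, 0.473 and 0.676 with an estimated correlation, and the complement genes C1s1 and C1ra were lower. Hspa1a was at 4.05 ± 0.727 TPM in PEG-MP and 687 ± 33.8 TPM in PEG-IM-MP, and Gdf15, a stress-induced cytokine, at 14.5 ± 3.07 and 772 ± 6.96 TPM. Saa3 was at 29653 ± 3681 and 299 ± 6.88 TPM, and C1s1, a protease of the classical complement pathway, at 142 ± 14.1 and 0.143 ± 0.0666 TPM. Il6 (log2 fold change 1.14, SE 0.130, adjusted p = 2.57e-05) and Cd80 (log2 fold change 2.56, SE 0.126, adjusted p = 9.61e-08) were higher in PEG-IM-MP and Ccl5 was lower (log2 fold change -2.51, SE 0.0838, adjusted p = 1.08e-08).

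The 6 largest rises were Tmem267 (7.87), Hspa1b (7.27), the growth factor Areg (7.11), Hspa1a (7.10), Gdf15 (5.66) and the growth factor Pgf (5.57). Assembled rather than annotated transcripts held 99.8% of the Tmem267 TPM, and its annotated transcripts were at 0.717 TPM in PEG-MP and 5.94 TPM in PEG-IM-MP. Areg was at 0.600 ± 0.201 and 219 ± 8.33 TPM and listed at 0 in each control library. The 6 largest falls were C1s1 (-6.96), Saa3 (-6.62), Ly6a (-6.51), the complement gene C1ra (-5.89), Ms4a4c (-5.88) and Ly6c1 (-5.77). Assembled transcripts held 70.1% of the C1ra TPM, and its annotated transcripts were at 48.3 TPM in PEG-MP and 0.743 TPM in PEG-IM-MP. Ms4a4c varied within PEG-MP, at 173 ± 117 TPM.

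Interferon-stimulated genes were lower in 38 and higher in 0 of 40 (34 and 2 after median-of-ratios scaling, camera adjusted p = 1.25e-05). Gbp2 stood at 254 ± 55.9 and 9.21 ± 0.387 TPM and Mx1 at 90.1 ± 16.7 and 2.90 ± 0.503 TPM. MHC class I genes were lower in 19 and higher in 1 of 22 (13 and 6 after scaling, camera adjusted p = 0.00950, which was 0.0943 after scaling), with Tapbp (-2.42) and Psmb8 (-2.21) lower. H2-K1 was lower as deposited (-0.25) and after quantile normalization (-0.49), and higher after median-of-ratios scaling (0.43). MHC class II genes were lower in 15 and higher in 2 of 17 (14 and 2 after scaling, camera adjusted p = 0.0219). These 3 lists had an adjusted p between 0.473 and 0.676 with an estimated correlation.

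Inflammatory cytokines were higher in 15 and lower in 4 of 22 (17 and 3 after scaling, camera adjusted p = 6.73e-05). Csf3, a granulocyte growth factor, stood at 1.48 ± 0.355 and 56.7 ± 6.56 TPM and Osm at 16.7 ± 1.97 and 215 ± 16.5 TPM. Il12b was higher (0.90), while Tnf (log2 fold change 0.03, SE 0.194, adjusted p = 0.895) and Il1b (log2 fold change 0.37, SE 0.174, adjusted p = 0.0745) were not past the threshold. Both passed after median-of-ratios scaling, with log2 fold changes of 0.69 and 1.05, and neither after quantile normalization (0.30 and 0.10), and Il1b passed without control replicate 1 (adjusted p = 0.00248) or control replicate 2 (0.0484). Chemokines were higher in 13 and lower in 5 of 20 (14 and 4 after scaling, camera adjusted p = 0.000452). Ccl3 stood at 211 ± 66.0 and 5018 ± 489 TPM and Cxcl10 at 10.2 ± 3.53 and 72.8 ± 2.62 TPM. Unfolded protein response genes were higher in 12 and lower in 3 of 21 (19 and 0 after scaling, camera adjusted p = 0.000149). The p53 and apoptosis genes were higher in 11 and lower in 7 of 21 (14 and 4 after scaling, 9 and 9 on annotated transcripts alone, camera adjusted p = 0.00526). Immediate early and heat shock genes were higher in 14 and lower in 5 of 22 (17 and 2 after scaling, camera adjusted p = 6.73e-05). Cytosolic ribosomal protein genes were higher in 28 and lower in 1 of 34 (34 and 0 after scaling, camera adjusted p = 4.57e-09, and 15 and 4 with an adjusted p of 0.107 after quantile normalization). The adjusted p lay between 0.473 and 0.676 for these 6 lists with an estimated correlation.

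Oxidative phosphorylation genes were lower in 28 and higher in 2 of 30 (12 and 8 after median-of-ratios scaling and 27 and 1 after quantile normalization, camera adjusted p = 0.00335, which was 0.596 after median-of-ratios scaling, while quantile normalization kept the call, and adjusted p = 0.270 with an estimated correlation). Cell cycle genes were lower in 28 and higher in 3 of 32 (26 and 4 after scaling, camera adjusted p = 0.0347, which was 0.0749 with a filter at 5 TPM, and adjusted p = 0.676 with an estimated correlation). Among maturation genes, 6 were higher and 14 lower of 24, with no call for the list (camera adjusted p = 0.991, 9 and 11 after scaling). Cd86 was higher (1.61) and Ccr7 lower (-0.58, 0.10 after median-of-ratios scaling and -0.62 after quantile normalization). Cd40 was not past the threshold (log2 fold change -0.85, SE 0.369, adjusted p = 0.0572, adjusted p = 0.00804 without control replicate 1 and 0.00457 without control replicate 3).

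Genes higher and then lower in PEG-IM-MP than in PEG-MP numbered 10 and 10 of 23 NF-kB pathway genes (camera adjusted p = 0.108, then 14 and 5 after scaling), 7 and 19 of 28 pattern recognition receptors (0.811, then 10 and 14), and 3 and 10 of 17 inflammasome genes (0.891, then 8 and 7). They numbered 6 and 20 of 28 phagocytosis genes (0.541, then 9 and 14), 4 and 16 of 23 cholesterol genes (0.811, then 8 and 12), and 4 and 14 of 20 lipid storage genes (0.949, then 9 and 8). For further lists they were 14 and 14 of 32 lysosome genes (0.108, then 20 and 11), 5 and 14 of 21 glycolysis genes (0.811, then 10 and 8), and 3 and 16 of 20 Nrf2 targets (0.14, then 5 and 12). Counts were 7 and 8 of 19 alternative activation genes (0.373, then 9 and 7) and 3 and 6 of 15 mitochondrially encoded genes (0.991, then 4 and 3). Of the markers of other cells they numbered 2 and 10 of 13 for macrophages (0.108, then 3 and 9 with an adjusted p of 0.0348), 2 and 8 of 14 for neutrophils (0.991, then 5 and 4), and 2 and 8 of 11 for mast cells (0.541, then 2 and 8). They numbered 0 and 6 of 6 for lymphocytes (0.192, then 0 and 6), 1 and 5 of 7 for plasmacytoid dendritic cells (0.811, then 3 and 4), and 2 and 8 of 12 for conventional dendritic cells (0.991, then 5 and 6). The last were 0 and 2 of 4 for erythroid cells (0.991, then 1 and 1) and 1 and 5 of 6 for stromal and epithelial cells (0.811, then 2 and 4). After quantile normalization the counts were 12 and 10 for NF-kB, 5 and 9 for inflammasome, 5 and 13 for lipid storage, 5 and 13 for glycolysis, 3 and 6 for mitochondrially encoded and 3 and 3 for neutrophil genes, and the phagocytosis (adjusted p = 0.027), Nrf2 (0.0076) and macrophage lists (0.00655) were called lower. The macrophage marker Adgre1 was at 357 ± 28.3 and 38.1 ± 3.78 TPM. Adjusted over the list alone the counts were the same but for the pattern recognition receptors with 8 and 19, the lysosome with 15 and 14 and the erythroid markers with 0 and 1. The median was negative while the test pointed up for the alternative activation, mitochondrially encoded, neutrophil and erythroid lists, and the mean was negative for the NF-kB and lysosome lists.

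limma called 10973 genes between the preparations, 2967 higher and 8006 lower in PEG-IM-MP, and 5782 at least 2-fold (1308 higher, 4474 lower), around a median log2 fold change of -0.56. After median-of-ratios scaling it called 10539, 5268 higher and 5271 lower, with 2640 and 2231 at least 2-fold, and after quantile normalization 10066, 4612 higher and 5454 lower.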

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

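The 4 tests of the retroviral transcripts, the splits of the libraries, and the spread by level with its intervals were chosen after the results were seen.

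Most genes had lower TPM in PEG-IM-MP than in control, with a median log2 fold change of -0.58. Without the 100 genes of highest mean TPM over all libraries the median was -0.577. Those genes held 38.8% of TPM in control and 40.8% in PEG-IM-MP, so leaving them out could hardly move the median. This removal therefore does not show which genes took up the scale. Genes called higher held 21.2% of TPM in control and 57.2% in PEG-IM-MP, and genes called lower held 68.5% and 32.2%. TPM has the same total in every library, so the share that some genes lost was held by others. Both sets were called on the same values. The shares do not tell whether the lower genes fell in amount or only relative to the rest. In the 8 quartiles of transcript length and GC content the highest median was -0.406, which argues against bias of length or GC content as the whole cause. Fewer reads in PEG-IM-MP left genes of at least 50 TPM undecided, with a median of -0.195 between the bounds set beforehand, but it would raise the spread of low genes, and their coefficient of variation at 2 to 5 TPM was 0.972 times the higher of the other groups (95% interval over 1000 resamples of the genes 0.918 to 1.03, and 0.926 to 1.06 against control), below the 1.2 times set beforehand. That spread followed the level in control (15.6% at 2 to 5 TPM and 5.05% at 50 TPM or more). Without the spread of abundant genes the ratio to control was 1.004 (0.935 to 1.08), which argues against reads fewer by enough to reach 1.2 times. Read totals are unknown, however, and PEG-IM-MP had fewer transcripts above 0 TPM (60500 ± 275, against 64312 ± 153 in control and 64882 ± 586 in PEG-MP), as fewer reads would also give. It also had fewer genes at 1 TPM or more (11555 against 12802 and 12766). The lower TPM of most genes gives this as well, so that count is no separate sign of depth. The intervals of these ratios resample genes and not libraries. They leave out the uncertainty of a spread estimated from 3 libraries per group, which limits the argument against fewer reads. A broad change of the RNA population with treatment stays open as a biological explanation and was not tested.

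Interferon-stimulated genes were lower in PEG-IM-MP than in PEG-MP in 38 of 40 genes. With median-of-ratios scaling 34 were still called lower, which argues against the scale of the TPM values as the whole cause. The list's median of -2.14 lay at percentile 0.01, the smallest that 10000 lists matched on mean TPM, length and GC content can give (their median was -0.35 and the lowest -1.04), which argues against length or GC bias. A different interferon response to the preparations may be the explanation, as a hypothesis found and tested on the same data. Ifnb1 itself was below the filter in all groups.

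Transcripts without a gene symbol lay outside the comparisons, and those whose deposited annotation matched retroviral proteins were above every control library in both treatments: their summed TPM was 1518 ± 49.2 in control, 2425 ± 226 in PEG-MP and 3926 ± 91.6 in PEG-IM-MP, of which matches to intracisternal A-particles held 737 ± 39.7, 822 ± 63.6 and 661 ± 9.0 and the others 781 ± 47.3, 1603 ± 163 and 3265 ± 100.4. RNA of stromal, epithelial or melanocytic cells carried by the vesicles stays open, because 0 genes of that list had at least 10 TPM and a 2-fold rise in both treatments, but 5 of 19 (Col1a1, Dcn, Lum, Krt8 and Krt18) were above every control library in both, Dcn at 0.0133, 12.5 and 3.06 TPM in control, PEG-MP and PEG-IM-MP and the others below 1 TPM, and the share such cells would need is unknown. The 4 loci of 297 that rose most gained 90% of the net rise or more in each treatment. Locus MSTRG.3602 alone gained 43.9% of it in PEG-MP and 48.9% in PEG-IM-MP. The net rise is what remains after the falls of other loci, so these are not shares of all rises. Of 210 such transcripts with a mean of at least 1 TPM, 71 lay above every control library in PEG-MP and 57 below. In PEG-IM-MP 80 lay above and 79 below. The large gains thus lay in few loci, while many other transcripts of the class moved both ways. Reads moved between copies of a repeat stay open, because the smaller ratio of the sums to control was 1.598, and for matches other than A-particles 2.053 with an SD of 0.244, not above 2 by more than its SD. Retroviral transcription that differs with treatment, or RNA brought by the vesicles from cells of another kind than these, may also account for it and was not tested.

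Transcripts without a symbol and without such a match summed to 6026 ± 947 TPM in control, 4737 ± 228 in PEG-MP and 8252 ± 373 in PEG-IM-MP, where every library was above every control library. Without loci MSTRG.22391 and MSTRG.22392 the sums were 6021 ± 947 in control and 5711 ± 154 in PEG-IM-MP, whose libraries (5534 to 5817) then lay within the range of the control libraries (5400.1 to 7112).

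Of 255 tested genes that the naming rule gives, 43 were called in opposite directions in the treatments against control with a called difference between them in limma, 33 of them also after median-of-ratios scaling and 40 after quantile normalization. Among those whose fold changes were followed through the alternatives, 25 did so, and the 5 with the largest difference come first. C1s1 rose by a log2 value of 4.46 in PEG-MP and was at -2.50 in PEG-IM-MP (difference -6.96, adjusted p = 5.50e-10). Ly6a was at 1.40 and -5.11 (difference -6.51), C1ra at 1.42 and -4.47 (difference -5.89), Ms4a4c at 2.94 and -2.93 (difference -5.88) and Ly6c1 at 1.32 and -4.45 (difference -5.77). Assembled transcripts held 70.1% of the C1ra TPM, and its annotated transcripts stood at 18.2, 48.3 and 0.743 TPM in control, PEG-MP and PEG-IM-MP.

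The other 20 had these differences between PEG-IM-MP and PEG-MP. Those higher in PEG-MP and lower in PEG-IM-MP than in control were Scd2 (-4.70), Gbp2 (-4.62), Mx1 (-4.54), Il4i1 (-3.69), Ifi47 (-3.38), Adgre1 (-3.20), G6pdx (-3.10), Psmb10 (-2.74), Marcksl1 (-2.52), Cybb (-2.52), Tapbp (-2.42), Pfkl (-2.42), Bst2 (-2.23), Psmb8 (-2.21), Ndufb3 (-1.71) and Ldha (-1.47). Those lower in PEG-MP and higher in PEG-IM-MP were Osm (3.61), Atp6v0d2 (2.81), Mfge8 (2.79) and Ctsl (2.01). After median-of-ratios scaling Bst2, Marcksl1 and Ldha were no longer called in opposite directions. After quantile normalization 24 of the 25 genes still were.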

How the results depend on the processing

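Annotated transcripts only, and list tests after median-of-ratios scaling, were chosen after the results were seen. Over the alternatives 5656 log2 fold changes of named genes kept direction and side of the threshold, 21 gained a call, 12 lost one and 20 reversed, and 1314 list tests were the same, 40 gained a call, 65 lost one and 69 reversed; the cause was not tested unless stated. Depth is unknown, so its limits cannot be given.

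Same-numbered libraries hardly deviated together (correlations -0.02 to 0.063 over 9 pairs, 0 over 0.1, and 1 library closest to its own number in both other groups). The highest correlations of all, 0.063, 0.055 and 0.047, were between same-numbered libraries, so weak pairing is not excluded. With the replicate number as a block, limma called 6215, 11249 and 10909 genes for PEG-MP against control, PEG-IM-MP against control and PEG-IM-MP against PEG-MP (1699, 6483 and 5800 at least 2-fold), 11969 in the F test and 39 lists (15, 13 and 11); the list calls of MHC class II (adjusted p = 0.06) and mitochondrially encoded genes (adjusted p = 0.0521) in PEG-MP against control ended.

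A pseudocount of 5, which shrinks changes of low genes by construction, left 981, 3797 and 3126 genes at least 2-fold. With an estimated correlation 0 lists were called in total and 0, 0 and 0 per comparison (6, 3 and 1 at an unadjusted p under 0.05), and with fry 85 (26, 29 and 30). At least 2-fold, 1149 genes were shared by the treatments. After median-of-ratios scaling 8715 of 11316 and 8238 of 10973 calls of PEG-IM-MP against control and PEG-MP were kept, with 811 and 735 called the opposite way, and 6336 of 6519 of PEG-MP against control. Leaving out each library gave 5560 to 6557, 10732 to 11254 and 10332 to 10903 genes (1562 to 1697, 6222 to 6477 and 5487 to 5785 at least 2-fold), 11520 to 11842 in the F test and 39 to 41 lists.

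Directions reversed as follows, with adjusted p for lists and log2 fold change for genes. With fry, which compares a list with no other genes, PEG-IM-MP against control reversed for MHC class I (0.00176), alternative activation (5.16e-06), cholesterol (0.00842), inflammasome (2.39e-05), lysosome (1.59e-06), conventional dendritic cell (1.37e-05), plasmacytoid (0.0304), stromal (0.0977) and Nrf2 (4.49e-05); PEG-MP against control for conventional dendritic cell (0.00304) and p53 (0.54); and PEG-IM-MP against PEG-MP for NF-kB (0.223), alternative activation (0.00411), lysosome (0.000316), mitochondrially encoded (0.000202), erythroid (0.0477) and neutrophil (0.000315). With median-of-ratios scaling, which lifts the typical gene of PEG-IM-MP, it reversed against control for alternative activation (0.917), ribosomal proteins (0.000636), Bst2 (0.29) and Csf1r (0.16), and against PEG-MP for lipid storage (0.91), glycolysis (0.906), inflammasome (0.98), conventional dendritic cell (0.98), erythroid (0.91), neutrophil (0.91), Car2 (0.57), Ccr7 (0.10), Csf1r (0.52), H2-K1 (0.43), Irf8 (0.35) and Pecam1 (0.28). With quantile normalization it reversed against control for MHC class I (0.385), alternative activation (0.562), lysosome (0.442) and Nrf2 (0.715), against PEG-MP for alternative activation (0.967), mitochondrially encoded (0.179), conventional dendritic cell (0.993), neutrophil (0.967), stromal (0.993), Car2 (0.30) and Pecam1 (0.51), and PEG-MP against control for immediate early (0.975) and phagocytosis (0.959). The most abundant transcript reversed H2-K1 (-0.034) and Pecam1 (-0.15) in PEG-IM-MP against control. In PEG-IM-MP against PEG-MP a pseudocount of 0.1 reversed maturation (0.992), a filter at 5 TPM conventional dendritic cell (0.868), and the block mitochondrially encoded, erythroid and neutrophil (0.996 each).

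Leaving out 1 library reversed, with the range over all 9 omissions, H2-Ab1 (-0.078 to 0.054) and Prss34 (-0.024 to 0.23) in PEG-MP against control, and Tnf (-0.17 to 0.24) and Car2 (-0.25 to 0.094) in PEG-IM-MP against PEG-MP, and 10 uncalled lists: phagocytosis (0.724 to 0.967), oxidative phosphorylation (0.845 to 0.996), p53 (0.814 to 0.981) and immediate early (0.724 to 0.9997) in PEG-MP against control, MHC class I (0.749 to 0.992) in PEG-IM-MP against control, and maturation (0.887 to 0.996), mitochondrially encoded (0.887 to 0.996), neutrophil (0.872 to 0.996), conventional dendritic cell (0.878 to 0.996) and erythroid (0.864 to 0.996) in PEG-IM-MP against PEG-MP.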

Other observations

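KEGG pathways of the deposited annotation were tested with limma's camera in an exploration chosen after the results were seen, as were the test with fry, their repeats under other scalings and the splits of the libraries. Of 304 pathways 45 were called for PEG-MP against control, 48 for PEG-IM-MP against control and 14 for PEG-IM-MP against PEG-MP, and 0 in each with an estimated correlation, where 19, 15 and 13 had an unadjusted p under 0.05. Of these called pathways 43, 42 and 14 were still called in the same direction after median-of-ratios scaling, and 39, 10 and 6 after quantile normalization. Limma's fry, which compares a pathway with no other genes, called 210, 288 and 288. Proteasome genes, which degrade proteins and make peptides for MHC class I, rose in 39 and fell in 3 of 49 in PEG-MP (adjusted p = 3.60e-08, and adjusted p = 0.66 with an estimated correlation). In PEG-IM-MP against control 11 were higher and 28 lower, without a call (adjusted p = 0.838). The IL-17 signaling pathway, whose members include many chemokines and cytokines, rose in 34 and fell in 9 of 70 in PEG-MP (adjusted p = 0.00224) and rose in 45 and fell in 20 in PEG-IM-MP (adjusted p = 6.22e-06, 50 and 14 after median-of-ratios scaling). With an estimated correlation these adjusted p were 0.66 and 0.608.

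Peroxisome genes were lower in 61 and higher in 8 of 74 in PEG-IM-MP than in PEG-MP (adjusted p = 0.0377, 44 and 16 after median-of-ratios scaling), and genes for the biosynthesis of unsaturated fatty acids were lower in 20 and higher in 1 of 23 (adjusted p = 0.0483, 19 and 3 after scaling). Collecting duct acid secretion, which holds subunits of the proton pump that acidifies vesicles, was higher in 11 and lower in 3 of 17 (adjusted p = 0.00263, 14 and 3 after scaling, and adjusted p = 0.0515 after quantile normalization, which ended the call). With an estimated correlation the adjusted p of these 3 pathways was 0.797.

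Some assembled loci without a symbol, chosen after their values were seen, were abundant in PEG-IM-MP. Locus MSTRG.22391, with no retroviral match, stood at 2.91 ± 0.726 TPM in control, 4.15 ± 0.25 in PEG-MP and 1522 ± 164 in PEG-IM-MP, and MSTRG.22392, also without a match, at 1.66 ± 0.237, 2.48 ± 0.281 and 1019 ± 136. Of loci with a retroviral match, MSTRG.3602 stood at 70.5 ± 1.05, 469 ± 79.5 and 1248 ± 59.2 TPM and MSTRG.5574 at 2.65 ± 0.133, 100.3 ± 6.98 and 488 ± 33.5 TPM.

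For each comparison the 6 libraries can be split in 10 ways, too few for a share under 0.05, and 1 split, the real one, gave counts as large. The real count and the highest of the other splits were 6519 and 1 genes, 1695 and 1 at least 2-fold and 17 and 14 lists for PEG-MP against control, 11316 and 2, 6478 and 2 and 13 and 11 for PEG-IM-MP against control, and 10973 and 1, 5782 and 1 and 11 and 10 for PEG-IM-MP against PEG-MP. Each of the other splits mixes libraries of both groups, so a difference between the groups enters the spread and lowers the gene count. Part of that difference also stays between the mixed groups, so the list counts are not those of unchanged groups. The counts of these splits therefore do not show what groups with no effect would give. For the F test 1 of 100 splits of the 9 libraries, the real one, gave as many as 12061 genes. That share is under 0.05 and the smallest that 100 splits can give, so such a count is rare among splits of these libraries. The replicates may be technical, so the splits do not exclude chance differences between cultures. The highest other split gave 9023, and whether it kept much of the groups together was not examined.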
